A study of Escherichia coli with 8 samples.

How the data were processed

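RecA is the bacterial strand exchange protein that coats single-stranded DNA and pairs it with a homologous duplex during repair. Its association with the chromosome of Escherichia coli was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq). Strain DL4184 carries a long DNA palindrome in lacZ (lacZ::pal246) and strain DL4201 has an intact lacZ. Per the labels, DL4184 underwent an induced chromosomal break and DL4201 did not, and both are proficient in recombination. Both derive from BW27784 and carry the sbcDC genes, which code for the SbcCD nuclease that cuts DNA hairpins, under an arabinose-inducible promoter. Cultures were grown at 37 °C in medium with 0.2% arabinose to an optical density of 0.2 to 0.25 and crosslinked with 1% formaldehyde for 10 min, per the labels' protocols. DNA recovered with an anti-RecA antibody (ChIP) and DNA of the same lysate without immunoprecipitation (input) were sequenced from 2 biological repeats of each strain, which gives 8 libraries in 4 groups.

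The values used are raw counts of reads in 4630 numbered bins of the chromosome, as deposited by the authors, with no normalization. The submitters' processing notes name Bowtie2, HTSeq and DESeq, without versions or roles. The genome build, the bin size and the handling of duplicate reads and of reads that match several places are not given in the sources used here. The column names give the strain, the assay and a letter A or B, and the labels give the repeat numbers 1 and 2. Letters and numbers are not tied to each other in any label, so each column was assigned to its group only, and letters serve as names. Letter-based pairs were not treated as paired in the main tests. Tests and distances planned for genes and kb before the data were examined were run on bins, since bins are what was counted.

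Bins carry no positions. They were placed along assembly ASM584v2 (strain K-12 MG1655), from which the names, starts and ends of genes were taken. Of the counts, the alignment used those of the input alone. Repeated genes (ribosomal RNA operons, insertion sequences, rhs and tuf genes) lose reads in the input, and 46 clusters of such genes were matched in order to dips of the summed input. The alignment assumed bins of about 1 kb in one direction along the reference and let the offset shift between clusters, so the 1.00 kb per bin obtained from the aligned clusters is not an independent estimate of the bin size. In 33 of the clusters over 50% of the input was lost. The alignment score was 31.5, against -14.8 for the best other rotation over 50 kb away. Leaving out each cluster in turn moved its predicted place by a median of 0.1 bin, by 0.92 bin at the 90th percentile and by at most 3.14 bins, and by at most 1.05 bins in the neighbourhood of lacZ. Steps of 3.2, 3.2 and 3.1 bins lay in the intervals that hold rhaDAB, araDAB and araHGF, the sugar operons removed in BW27784, which span 4.0, 4.2 and 3.6 kb in the reference. Clusters that lost almost none of their input follow the offset of their neighbours, so their small shifts say little about accuracy. Near lacZ a bin named by a gene is taken as that gene's bin to within about 1 bin. Elsewhere the error may be larger, as the shift of up to 3.14 bins shows. Of the 4651 genes in the table, 4642 were placed. The middle of lacZ fell in bin 1074, and its gene body in bins 1072 to 1075. Lower bin numbers on this arm lie toward the replication origin. Ribosomal RNA bins hold only the part of their reads that could be counted, and their values are uncertain for that reason, as are those of insertion sequences and other repeated genes.

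Bins were filtered with filterByExpr by group, which kept 4608 and left out 22, of which 21 had 0 counts in all libraries. Counts were scaled by TMM factors and tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) by the quasi-likelihood F test in a fit of all 8 libraries with 4 group means and no block. P-values were adjusted by the Benjamini-Hochberg method over all tested bins, and bins with an adjusted p under 0.05 were called. The standard error (SE) of a log2 difference is its size divided by the square root of F. The comparison of RecA enrichment is the difference between the strains in log2 ChIP over input. Further contrasts were ChIP between strains, input between strains, and ChIP over input within each strain. Changes are relative to the bulk of bins, because TMM sets the typical bin to no change.

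ChIP/input ratios of single libraries are the share of ChIP counts in a bin over the share of the pooled input counts of the strain, each share taken relative to the counts of bins over 500 bins from lacZ. The plan had named the input of the same culture, which cannot be identified by column letters, so both inputs of the strain were pooled. Ratios in windows of bins use summed counts. The extent around lacZ is the run in which every sliding window of 11 tested bins held at least 6 bins called higher. Runs of at least 5 neighbouring bins called in the same direction were sought over 500 bins from lacZ. Zones were defined after the data were seen. In the comparison of the strains a zone was a stretch of at least 6 called bins with gaps of at most 3 bins between neighbouring calls. In DL4201 a zone was a run of at least 12 tested bins in a row called higher than input.

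Gene lists were fixed before the data were examined and were tested with camera (preset correlation of 0.01, and estimated correlation) and fry, adjusted over the lists within a contrast. They comprise the loci of the genotype, the break flanks on either side of lacZ, the LexA-controlled (SOS) regulon, recombination and break repair genes, ribosomal proteins, ribosomal RNA genes, other highly transcribed genes, the Rac, DLP12, Qin, e14 and CP4-6 prophages, AT-rich surface polysaccharide genes, and the loci deleted in BW27784. A list is counted in bins, and a bin shared by several members is counted once. The list of deleted loci had 0 members placed and could not be tested. Bins named below were chosen by a rule fixed in advance. It takes up to 10 bins with the largest rise and 10 with the largest fall that were called and had the same sign in all 4 pairings of a DL4184 with a DL4201 library, each ChIP library taken against both inputs of its strain. It adds every locus of the genotype, up to 4 members of each list by smallest p, recA, lexA and the ends of the extent. In the other contrasts it takes up to 5 rises and 5 falls, the loci of the genotype, recA and lexA. Other bins were named after their values were seen.

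The test of RecA enrichment was checked on simulated data, in negative binomial counts drawn with the mean of each assay over both strains and with the library sizes and dispersions of the fit. Of 50 bins each changed 1.5-fold, 2-fold, 4-fold and 0.5-fold among 4608, the test recovered 42, 49, 50 and 49, and it also called 12 unchanged bins. Total counts ran from 2736295 to 7114727 per library, and the counting error at the median bin was between 2.63% and 4.85%. Reads carry no molecular identifiers here, so these percentages cover counting error only. Alternatives covered the scaling, the test (DESeq2 1.42.0, limma-voom), the filter, the thresholds, the libraries in the fit, a replicate block and leaving out each library. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Recombination hotspot sequences and other features that need a genome sequence were not analysed here.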

Results

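RecA ChIP-seq was measured in 2 strains of Escherichia coli K-12, with ChIP and input libraries from 2 repeats of each that the labels call biological. DL4184 carries the palindrome in lacZ and received the induced break, and DL4201 carries an intact lacZ and did not. The ChIP libraries of DL4184 held 2736295 counts (A) and 3038124 counts (B), and its input libraries 6347113 (A) and 7114727 (B). For DL4201 the ChIP totals were 3171898 (A) and 4320250 (B), and the input totals 5972567 (A) and 6963846 (B). The median tested bin held between 425 and 741 counts in the ChIP libraries and between 1216 and 1441 in the input libraries. Bins within 50 bins of lacZ took 8.27% and 14.4% of the ChIP counts of DL4184, and 1.94% and 1.88% of those of DL4201. In the inputs the same bins took between 2.11% and 2.13%. The variation between both libraries of a group exceeded counting error, with a chi-square per degree of freedom of 17.7 for DL4184 ChIP, 5.07 for DL4201 ChIP, 1.38 for DL4184 input and 2.69 for DL4201 input. These values cover all tested bins. For DL4184 ChIP they therefore include the bins near lacZ, where its libraries differed in share (8.27% and 14.4%).

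The main comparison asks where on the chromosome the break changed the association of RecA with DNA, as the difference between the strains in ChIP over input. RecA enrichment rose most at and beside lacZ. The bin that holds the end of lacZ and lacY, the lactose permease gene (bin 1072), rose by 4.90 ± 0.444 (log2 ± SE, n = 2 libraries per group, adjusted p = 0.000207), with ChIP/input ratios of 13.2 and 29.1 in DL4184 against 0.818 and 0.642 in DL4201. On the origin-proximal side lacA/lacY rose by 4.83, codA (cytosine deaminase) by 4.69 and cynR by 4.62. On the origin-distal side the mhp genes of phenylpropionate degradation rose by 4.54 at mhpB/mhpC (bin 1080), 4.52 at mhpD/mhpF, 4.34 at mhpF/mhpE and 4.33 at mhpA/mhpB. These bins, together with bin 1073 in lacZ (4.63) and codB/codA (4.51), were the 10 largest rises. Each of the 10 had an adjusted p of 0.000207 and the same sign in all 4 pairings of libraries. The list of the origin-proximal flank had 17 of 18 bins called higher (18 when adjusted over the list alone; median 3.62; camera adjusted p = 1.12e-102, adjusted p = 0.0384 with an estimated correlation). Further members were prpD with 4.21, codB with 4.20, prpC with 3.90 and prpB with 3.65. The list of the origin-distal flank had 20 of 20 bins called higher (20 when adjusted over the list alone; median 2.77; camera adjusted p = 7.69e-91, adjusted p = 0.0384 with an estimated correlation), among them mhpT with 4.23 and mhpA with 4.11. Over the chromosome 175 bins were called higher and 5 lower of 4608 tested, and 131 of the higher bins exceeded 1.5-fold. With total counts as the only scaling the median of all bins shifted by -0.213 and the calls became 147 higher and 1251 lower, so changes are given relative to the bulk of bins.

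**Figure D1:**
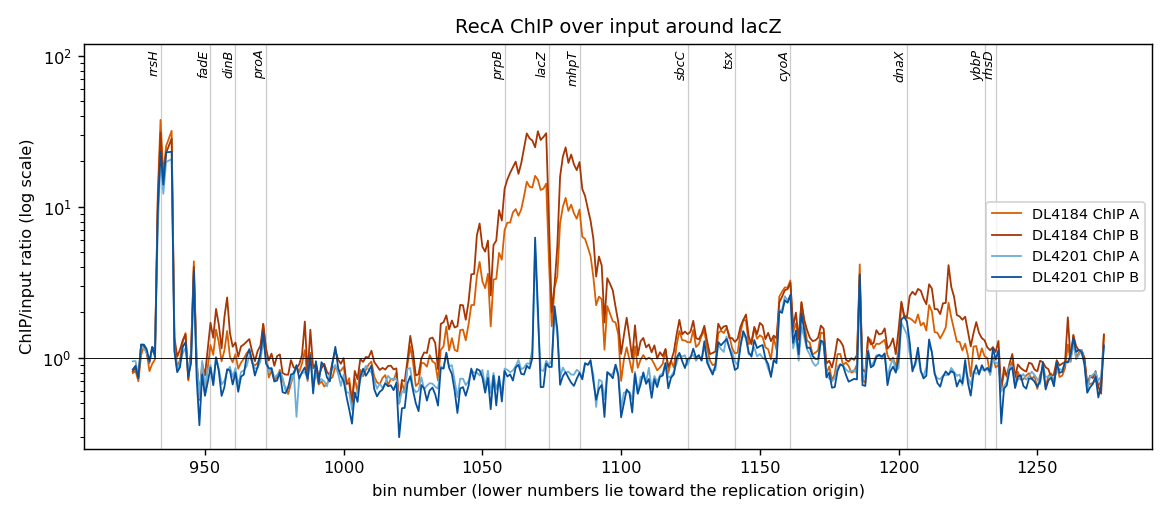
ChIP/input ratio (log axis) of the 4 ChIP libraries by bin around lacZ, each scaled to bins over 500 bins from lacZ, with gene positions marked. Both DL4184 libraries rise on either side of lacZ, to 13.2 and 29.1 in bin 1072, where the DL4201 libraries lie at 0.818 and 0.642.

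Between these high flanks lay a narrow stretch of lower enrichment over the middle of lacZ and lacI, the gene of the lac repressor. The middle of lacZ (bin 1074) rose by 2.81 ± 0.279 (adjusted p = 0.000207), with ratios of 4.33 and 7.68 in DL4184 and 0.895 and 0.871 in DL4201. The next bin, which holds the other end of lacZ and the start of lacI (bin 1075, named after its values were seen), rose by 1.03 ± 0.117 (adjusted p = 0.00056). In lacI (bin 1076) the rise was 0.55 ± 0.11 (adjusted p = 0.0202), and in mhpR, which codes for the activator of the mhp genes, it was 1.62 ± 0.221 (adjusted p = 0.00179). Ratios in DL4201 were also above 1 there, which lowers the difference. At lacI they were 1.99 and 2.2, against 2.91 and 3.04 in DL4184, and at mhpR 1.45 and 1.54 against 3.47 and 5.48. The call for lacI was lost without any 1 of the 4 input libraries, with adjusted p between 0.063 and 0.169. Of the other loci in the genotype, sbcD and sbcC, whose products form the SbcCD nuclease, rose by 0.62 ± 0.108 (adjusted p = 0.00878) and 0.56 ± 0.115 (adjusted p = 0.0222). The call for sbcD was lost without DL4184 input B (adjusted p = 0.0635) or DL4201 input A (adjusted p = 0.0529). That for sbcC was lost without DL4184 input B (adjusted p = 0.133), DL4201 input A (adjusted p = 0.12) or DL4201 ChIP A (adjusted p = 0.0883). The bin of cynX was not called by edgeR (1.86 ± 0.462, adjusted p = 0.0578), although its ratios were 16.1 and 24.8 in DL4184 and 5.32 and 6.26 in DL4201. It was called by DESeq2 (adjusted p = 7.03e-09), by limma-voom (adjusted p = 0.0017) and with total counts only (adjusted p = 0.0218), and also without DL4184 ChIP A (adjusted p = 0.000142) or without DL4184 ChIP B (adjusted p = 0.00376). proA (0.30, adjusted p = 0.0805) and tsx (0.45, adjusted p = 0.0883) were not called by edgeR. tsx was called by DESeq2 (adjusted p = 0.0115) and without DL4184 ChIP A (adjusted p = 0.0209), and proA with TMM from bins over 500 bins from lacZ (adjusted p = 0.0473). The list of genotype loci thus had 5 of 8 bins called higher (7 by DESeq2, 6 by limma-voom, 8 when adjusted over the list alone; median 0.59; camera adjusted p = 1.12e-13, adjusted p = 0.0509 with an estimated correlation), and it shares lacI, mhpR and cynX with the flanks.

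The stretch of raised RecA enrichment around lacZ reached 53 bins toward the origin and 44 bins away from it. It ended at ykgL/ykgO/ykgM (bin 1021, 0.44, adjusted p = 0.168) on the origin-proximal side and at aroM/ppnP (bin 1118, 0.40, adjusted p = 0.0269) on the other. Of its 98 bins, 86 were called higher and 12 were not called, and the median was 1.62. Further raised zones lay beyond it. The largest (bins 1201 to 1230) ran from ybaN/apt to ybbA/ybbP on the origin-distal side and held recR, hemH, ushA and copA, with 25 of 30 bins called and a median of 1.19. It peaked at ybaP/ybaQ/copA (bin 1218), which rose by 2.09 ± 0.272 (adjusted p = 0.00141), with ratios of 2.32 and 4.12 in DL4184 and 0.773 and 0.775 in DL4201. On the origin-proximal side a zone from fadE to prfH/pepD (bins 952 to 964) had 11 of 13 bins called and a median of 0.78, and held dinB and dinJ/yafQ. Lower zones lay at aroM to proY (12 of 14 bins, median 0.49), which begins in the last bin of that stretch and continues it, queA to cyoB (12 of 23, median 0.41) and tesB to acrR/mscK (9 of 12, median 0.43). The origin-distal extent depends on the libraries and the rule: it was 89 bins without DL4184 ChIP A, 94 by DESeq2 calls and 71 with a window of 21 bins.

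Summed over windows, the difference in RecA enrichment was largest up to 25 bins from lacZ and near 1-fold from 200 bins on. In the 11 bins from the middle of lacZ toward the origin the log2 ChIP/input ratio was 4.17 ± 0.711 (SD, n = 2) in DL4184 and 0.84 ± 0.0699 in DL4201, a 10-fold difference (3.33). As a median over bins it was 4.52, and the next window was then lower (3.03). The sum includes cynX, with its ratios of 5.32 and 6.26 in DL4201. From 10 to 25 bins it was 2.93 ± 0.656 against -0.43 ± 0.0772, 10.3-fold higher, and from 25 to 50 bins 0.66 ± 0.37 against -0.50 ± 0.0928, 2.25-fold higher. On the origin-distal side the values were 3.43 ± 0.724 against -0.02 ± 0.0366 in the 10 bins beside it, which is 11-fold (4.09 as a median over bins). From 10 to 25 bins they were 2.28 ± 0.604 against -0.36 ± 0.0332, 6.23-fold higher, and from 25 to 50 bins the difference was 1.5-fold. From 50 to 100 bins it was 1.27-fold there and 1.15-fold on the origin-proximal side. Beyond that the sides differed in value: from 100 to 200 bins, where the zone at copA lies, the origin-distal difference was 1.45-fold with 36 of 100 bins called, and the origin-proximal one 1.15-fold with 11 of 99. Whether the sides differ was not tested. From 200 to 500 bins the differences were 0.998-fold and 1.06-fold. With camera, the windows up to 200 bins passed the threshold on both sides (largest adjusted p = 2.47e-05) and those from 200 to 500 bins did not (adjusted p = 0.177 and 0.0945). By fry the origin-distal window from 200 to 500 bins did pass (adjusted p = 0.0162), and the origin-proximal one did not (adjusted p = 0.997). With camera and an estimated correlation the windows up to 50 bins still passed on both sides (largest adjusted p = 0.0446). From 50 to 100 bins the origin-distal window passed (adjusted p = 0.0446) and the origin-proximal one did not (adjusted p = 0.253), and from 100 to 200 bins neither did (adjusted p = 0.0806 and 0.0916 with an estimated correlation).

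**Figure D2:**
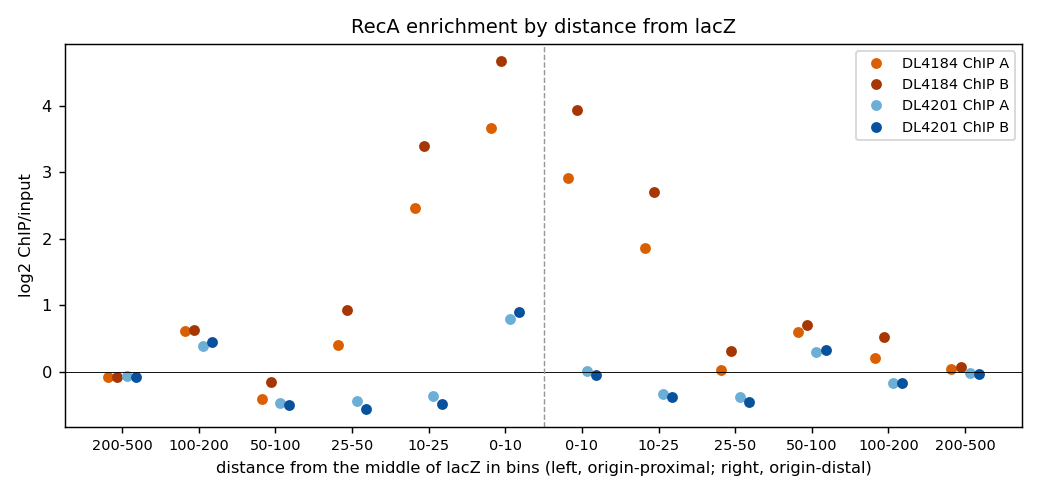
Log2 ChIP/input ratio of the 4 ChIP libraries in windows of distance from lacZ on each side, by summed counts. Both DL4184 libraries lie above both DL4201 libraries up to 200 bins on each side, by 3.33 in the mean of the first origin-proximal window. From 200 to 500 bins they do so on the origin-distal side only, by a small difference.

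Away from lacZ, recA and lexA, the genes of the recombinase and of the SOS repressor, rose. recA rose by 0.75 ± 0.131 (adjusted p = 0.00907), with ratios of 2.89 and 2.44 in DL4184 and 1.59 and 1.68 in DL4201. lexA rose by 0.59 ± 0.102 (adjusted p = 0.00828), with ratios of 1.74 and 1.59 against 1.15 and 1.15. The call for recA was lost without any 1 input library, although the difference then stayed between 0.732 and 0.766. Inputs and ChIP libraries share a common spread per bin in the fit, and leaving out an input changes that spread. That for lexA was lost without DL4184 input A (adjusted p = 0.0571), DL4184 input B (0.0805) or DL4201 input A (0.0651). The list of the SOS regulon had 6 of 31 bins called higher (10 when adjusted over the list alone; median 0.10; camera adjusted p = 0.000731, adjusted p = 0.17 with an estimated correlation). By fry its adjusted p was 0.0108, and 0.0915 with blocks by column letter. The others were recN (0.41 ± 0.0842, adjusted p = 0.0215) and, in the raised zone near lacZ, dinJ/yafQ (0.83), dinB (0.53) and the bin of yafN and yafO (0.62). The call for recN was lost without DL4184 input A (adjusted p = 0.132), DL4184 input B (0.112), DL4201 input A (0.12) or DL4201 ChIP B (0.0597). That for the bin of yafN and yafO was lost without DL4184 input B (0.0778) or DL4201 input B (0.072). With total counts only, recA (0.53, adjusted p = 0.0208) and lexA (0.37, adjusted p = 0.0366) were still called, recN was not (adjusted p = 0.155), and the list's median was -0.12. Recombination and repair genes had 5 of 41 bins called higher (7 when adjusted over the list alone), at recA and recN and, in the raised zones 50 to 130 bins from lacZ, at sbcC, sbcD and recR (0.94). This list had a median of -0.02 and a mean of 0.08, and camera gave an upward direction with an adjusted p of 0.752. The call for recR was lost without DL4184 input A (adjusted p = 0.0609), DL4201 input A (0.0645), DL4201 input B (0.0729) or DL4201 ChIP A (0.0766). The list shares recA, recN and other genes with the SOS list.

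**Figure D3:**
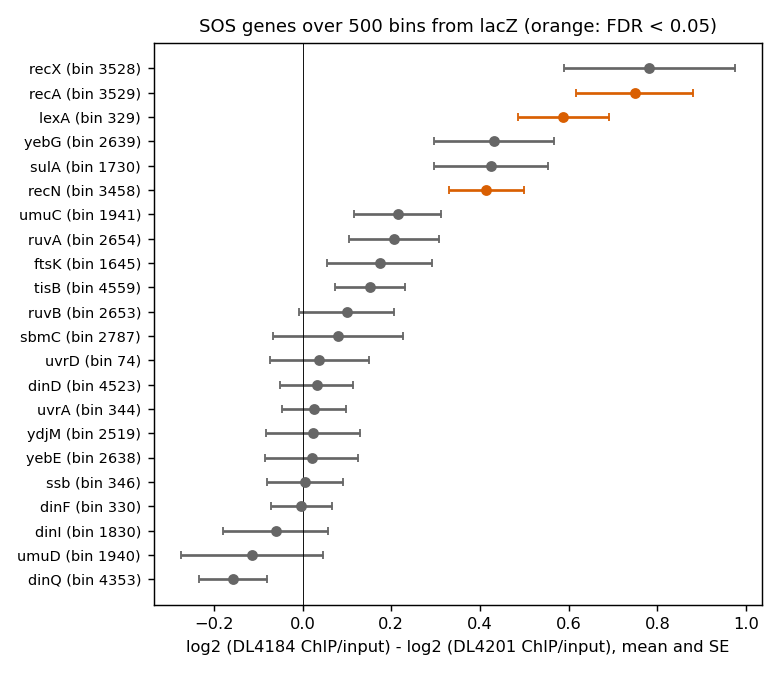
Log2 difference between the strains in ChIP over input (mean and SE) at the 22 bins of SOS genes over 500 bins from lacZ. recA, lexA and recN, in orange, passed an adjusted p of 0.05, at 0.75, 0.59 and 0.41.

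Among the remaining lists, few bins changed between the strains. Ribosomal protein genes had 2 of 37 bins called higher (2 when adjusted over the list alone; median 0.285; camera adjusted p = 0.000731, adjusted p = 0.614 with an estimated correlation), at rpmI (0.53) and rpmE (0.39). The call for rpmI was lost without any 1 of the input libraries or DL4201 ChIP A (highest adjusted p = 0.296 without DL4184 input B). That for rpmE was lost without any 1 of the input libraries, DL4201 ChIP A or DL4201 ChIP B (highest adjusted p = 0.251 without DL4184 input B). With total counts only neither was called (adjusted p = 0.0847 and 0.176), and limma-voom did not call rpmE (0.0704). Ribosomal RNA genes had 0 of 13 bins called by edgeR, with 3 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom, and 0 when adjusted over the list alone. Their median was 0.449 (camera adjusted p = 0.00586, adjusted p = 0.614 with an estimated correlation), and rrsB (adjusted p = 0.0108), rrlE (0.0394) and rrsH (0.0317) were called without DL4184 ChIP B. The CP4-6 prophage, whose bins lie 69 to 101 bins from lacZ on the origin-proximal side, had 1 of 19 bins called higher (3 when adjusted over the list alone; median 0.2; camera adjusted p = 0.00795, adjusted p = 0.614 with an estimated correlation). That bin, at intF (0.47, adjusted p = 0.0354), lost its call without any 1 of the input libraries, DL4184 ChIP B or DL4201 ChIP A (highest adjusted p = 0.169, without DL4184 input B). It was not called with total counts only (0.0835). By edgeR 0 bins were called, also when adjusted over the list alone unless stated, in other highly transcribed genes (of 32; 4 at an unadjusted p under 0.05; 1 by DESeq2, 0 by limma-voom; median 0.0874), Rac (of 17; 2, 0 and 0; 0.179) and DLP12 (of 15; 3, 0 and 0; 0.241). The same holds for Qin (of 18; 0, 0 and 0; median 0.02), e14 (of 13; 2, 1 and 0; 0.138; 1 when adjusted over the list alone) and the AT-rich polysaccharide genes (of 15; 1, 0 and 0; 0.257). Their camera adjusted p ran from 0.0773 (DLP12) to 0.877 (Qin, downward although its mean was 0.07). Without bins within 500 bins of lacZ, an alternative chosen after seeing the data, camera passed the AT-rich genes (adjusted p = 0.000472), Rac (0.000603), e14 (0.0012) and other highly transcribed genes (0.00523), and with an estimated correlation their adjusted p was between 0.335 and 0.539. With total counts only, the medians of other highly transcribed genes (-0.13), Rac (-0.04), Qin (-0.20), e14 (-0.08) and CP4-6 (-0.02) were negative. The median of all bins was then itself negative, as given above, and none of these lists lay below it.

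Compared directly, without input, the ChIP libraries of the strains differed most at the same bins beside lacZ. lacY/lacZ (bin 1072) rose by 4.86 ± 0.346 (adjusted p = 1.55e-05), codA by 4.81, lacA/lacY by 4.77, cynR by 4.66 and lacZ (bin 1073) by 4.65. All 8 genotype loci rose, among them cynX by 1.33 (adjusted p = 0.0327), tsx by 0.44 and proA by 0.41. With total counts only, tsx (0.219) and proA (0.181) lost their call. recA rose by 0.86 ± 0.0934 (adjusted p = 0.000213) and lexA by 0.63 (adjusted p = 0.000339). The largest falls were at yeaW/yeaX with -0.44, dmlA/yeaV with -0.43, the chemotaxis and motility genes cheA/motB with -0.42, wzxC/wcaJ with -0.40 and hybB/hybA with -0.38. In all, 335 bins were called higher and 55 lower, of which 56 and 55 lay over 500 bins from lacZ. With total counts only the split was 195 higher and 2222 lower at an all-bin median of -0.218, and SOS genes had 8 bins higher and 6 lower. With only the ChIP libraries in the fit 203 bins were called higher and 1 lower. The 5 falls named above were then not called (adjusted p between 0.0639 and 0.119), nor were lacI (0.0571) and cynX (0.318). Without DL4201 ChIP A the count was 239, and neither the 5 falls (adjusted p between 0.0729 and 0.135) nor cynX (0.208) were called. cynX also lost its call without DL4201 ChIP B. Without any 1 input library it lost its call too, at an unchanged 1.33, since inputs enter this contrast only through the common spread. tsx lost its call without DL4184 ChIP B or DL4201 ChIP B. Both flank lists had every bin called (18 of 18 and 20 of 20, adjusted p = 0.0384 with an estimated correlation for each). SOS genes had 10 of 31 bins called higher (11 when adjusted over the list alone; camera adjusted p = 2.19e-05, adjusted p = 0.0915 with an estimated correlation). CP4-6 had 5 of 19 (14 when adjusted over the list alone; camera adjusted p = 8.69e-05, adjusted p = 0.36 with an estimated correlation). Ribosomal proteins had 4 of 37 (camera adjusted p = 5.14e-05, adjusted p = 0.748 with an estimated correlation). Ribosomal RNA genes had 0 of 13 by edgeR, 8 at an unadjusted p under 0.05, 6 by DESeq2 and 0 by limma-voom (camera adjusted p = 0.00463, adjusted p = 0.748 with an estimated correlation). This comparison shares its ChIP libraries with the previous one.

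The input libraries tell whether DNA copy number differed between the strains. No bin passed the test: edgeR called 0 bins higher and 0 lower of 4608, with 52 at an unadjusted p under 0.05 and 230 expected by chance, and DESeq2 and limma-voom called 0. The edgeR fit shared its spread with the more variable ChIP libraries, so small input differences could be missed. The difference was -0.05 ± 0.194 at the middle of lacZ and -0.53 ± 0.327 at cynX, each with an adjusted p of 1. With camera 7 lists passed, with medians between -0.118 (AT-rich polysaccharide genes) and 0.0724 (CP4-6). With an estimated correlation 0 of the lists passed (smallest adjusted p = 0.538). The log2 ratio of input near the origin (mnmG) over that near the terminus (hipA) was 1.68 and 1.67 in DL4184 and 1.65 and 1.57 in DL4201. The means were 1.68 ± 0.00475 (SD, n = 2) and 1.61 ± 0.0538, a difference of 0.0706 (exact permutation test, 2-sided p = 0.333, which is the smallest p that 2 against 2 libraries allow). Along the chromosome the input difference changed by -0.0348 ± 0.002 (SE across bins, which are not independent replicates) per 1000 bins on the replichore with lacZ and by -0.0235 ± 0.00177 on the other. Over 500 bins from lacZ there were 0 runs of at least 5 neighbouring called bins in RecA enrichment, where the longest run was 2, and 0 in the input.

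Within each strain, ChIP over input shows where RecA signal lay in cells with and without the break. In both strains the highest values were at ribosomal RNA genes. rrlA reached 5.59 ± 0.242 in DL4184 and 5.05 ± 0.236 in DL4201, rrsH 5.44 and 4.75, rrlH 5.24 and 4.75, and rrlC 5.23 and 4.73. Their counts are those of repeated genes and therefore uncertain. The ribosomal RNA list had 13 of 13 bins called higher in each strain (median 4.95 in DL4184, adjusted p = 0.148 with an estimated correlation, and 4.54 in DL4201, adjusted p = 0.117 with an estimated correlation). Ribosomal protein genes had 37 of 37 in each (2.18, adjusted p = 0.235 with an estimated correlation, and 1.88, adjusted p = 0.31 with an estimated correlation). Of the 32 bins of other highly transcribed genes, 26 were higher and 1 lower in DL4184 (0.96, adjusted p = 0.324 with an estimated correlation). In DL4201 28 were higher and 1 lower (0.886, adjusted p = 0.546 with an estimated correlation). The Qin prophage had 14 of 18 bins called higher in DL4184 (0.81, adjusted p = 0.569 with an estimated correlation), and in DL4201 14 higher and 1 lower (0.824, adjusted p = 0.546 with an estimated correlation). With the preset correlation, camera passed all of these lists in both strains (largest adjusted p = 0.00519, Qin in DL4184). They also passed by fry (largest adjusted p = 0.00663, Qin in DL4201).

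The lowest ChIP over input lay at tyrB/yjbS, with -1.38 ± 0.193 in DL4184 and -1.41 ± 0.176 in DL4201, and at yfdH/yfdI, with -1.30 and -1.43. In DL4184 yjgL (-1.09) and rhsB (-1.23) and in DL4201 yjcF (-1.25) and yqiG (-1.23) followed, together with insB5 in both. AT-rich polysaccharide genes had 1 bin higher and 3 lower of 15 in DL4184, and 9 lower in DL4201 (median -0.442, camera adjusted p = 0.0246, adjusted p = 0.594 with an estimated correlation). DLP12 had 2 higher and 5 lower of 15 in DL4184, and 1 higher and 10 lower in DL4201 (camera adjusted p = 0.0317, adjusted p = 0.546 with an estimated correlation). CP4-6 had 3 higher and 3 lower of 19 in DL4184, and 0 higher and 8 lower in DL4201 (camera adjusted p = 0.0182, adjusted p = 0.546 with an estimated correlation). The e14 list had 1 higher and 2 lower of 13 in DL4184 and 6 lower in DL4201, and Rac 2 higher and 1 lower of 17 in DL4184 and 1 higher and 8 lower in DL4201. SOS genes had 16 bins higher and 7 lower of 31 in DL4184 and 13 and 9 in DL4201. Recombination genes had 23 higher and 7 lower of 41 in DL4184 and 23 and 2 in DL4201 (camera adjusted p = 0.0426, adjusted p = 0.546 with an estimated correlation). recA lay at 1.75 in DL4184 and 1.00 in DL4201, and lexA at 1.07 and 0.48. The flanks of lacZ had 18 of 18 and 20 of 20 bins higher in DL4184 (camera adjusted p = 8.71e-14 and 9.32e-14, fry adjusted p = 0.00232 for each, adjusted p = 0.324 with an estimated correlation for each). In DL4201 they had 2 higher and 2 lower of 18, and 2 higher and 1 lower of 20. Genotype loci had 8 of 8 higher in DL4184 (camera adjusted p = 1.19e-06, adjusted p = 0.235 with an estimated correlation). In DL4201 they had 5 of 8 (camera adjusted p = 0.0317, adjusted p = 0.546 with an estimated correlation). There the middle of lacZ lay at 0.10 (adjusted p = 0.666), cynX at 2.82, lacI at 1.35 and mhpR at 0.87. In all, 1639 bins were higher and 1559 lower in DL4184, and 1498 and 1401 in DL4201. With total counts only, SOS genes had 5 bins higher and 18 lower in DL4184 and 5 and 17 in DL4201, and recombination genes 12 and 25 in DL4184 and 8 and 15 in DL4201. Over all bins the splits were then 710 and 3276 (all-bin median -0.52) and 790 and 2842 (-0.304).

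**Figure D4:**
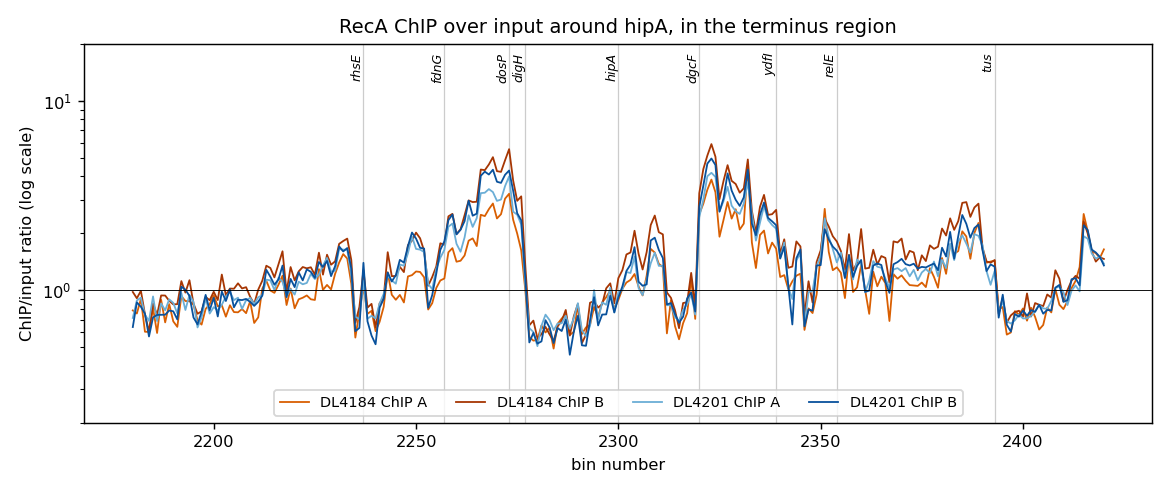
ChIP/input ratio (log axis) of the 4 ChIP libraries by bin around the terminus, scaled to bins over 500 bins from lacZ. Of the 5 zones called in DL4201 within 100 bins of hipA, those in bins 2255 to 2277 and 2320 to 2342 had the highest median ratios, with 2.41 and 2.54 in DL4201 for the first.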

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

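All tests of explanations in this part, and the fits of these bins without 1 library, were chosen only after the result was seen. The bins named here differ between the strains in ChIP over input, by the test of that difference, and lie over 500 bins from lacZ. Those called higher were recA with 0.749, yjdN with 0.678, the end of recN with bamE and yfjF (bin 3459) with 0.653, lexA/dinF with 0.588, tcyP beside the SOS gene ydjM with 0.577 and rpmI/infC/thrS with 0.528. Further ones were dinI/pyrC (bin 1831) with 0.469, gcvA/gcvB/ygdI with 0.459, recN (bin 3458) with 0.414, rpmE/yiiX/metJ with 0.39 and ftsK (bin 1646) with 0.364. The bins that stand for dinI (bin 1830, -0.0607), ydjM (bin 2519, 0.0237) and ftsK (bin 1645, 0.174) in the SOS list were not called. In this paragraph dinI and ftsK mean bins 1831 and 1646. Those called lower were metH with -0.332, php/yhfW with -0.346, nanK/nanE with -0.359, yiaV/yiaW with -0.379 and yeaW/yeaX with -0.49. Only bin 3459 was called in all 8 fits that leave out 1 library (highest adjusted p = 0.0114, without DL4201 input A). In those fits every bin kept its direction, with recA between 0.592 and 0.888, lexA between 0.493 and 0.677 and yeaW/yeaX between -0.559 and -0.422. yjdN moved most, from 0.426 (without DL4184 ChIP B) to 0.888 (without DL4184 ChIP A). Apart from bin 3459, calls were lost in some of the fits. recA was lost without any 1 input library (highest adjusted p = 0.0651, without DL4201 input A). lexA was lost without DL4184 input A, DL4184 input B (highest, 0.0805) or DL4201 input A. recN in bin 3458 was lost without DL4184 input A (highest, 0.132), DL4184 input B, DL4201 input A or DL4201 ChIP B. tcyP was lost without DL4184 input B (highest, 0.125), DL4201 input B or DL4201 ChIP A. dinI and ftsK were lost without any library other than DL4184 ChIP B (highest, 0.16 and 0.19 without DL4184 input B and A). yjdN and rpmE were lost without any input library or any DL4201 ChIP library (highest, 0.207 without DL4201 input B and 0.251 without DL4184 input B). rpmI and gcvA were lost without any input library or DL4201 ChIP A (highest, 0.296 and 0.188 without DL4184 input B). Of the falls, yeaW/yeaX and nanK/nanE were lost without any library other than DL4184 ChIP A (highest, 0.233 without DL4184 input B and 0.167 without DL4201 input B). php/yhfW was lost without any library other than DL4201 ChIP B (highest, 0.228 without DL4184 input B). metH was lost without any input library, DL4184 ChIP A or DL4201 ChIP A (highest, 0.205 without DL4184 input A). yiaV/yiaW was lost without DL4184 input A, DL4184 input B or DL4201 input B (highest, 0.096). By limma-voom the falls at yeaW/yeaX (0.0799), nanK/nanE (0.0569), php/yhfW (0.0747) and metH (0.0704) were not called.

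Some SOS genes away from lacZ were higher in DL4184. At their own bins 3 of 22 were called and 4 lay below 0 (median 0.0902). Without bins near lacZ, the SOS list had a camera adjusted p of 2.79e-06, 0.335 with an estimated correlation and 0.243 by fry. Ribosomal protein genes (2.27e-10) and ribosomal RNA genes (1.08e-05) also passed by camera, each with 0.335 when estimated. So did lists not chosen for high transcription, namely AT-rich polysaccharide genes (0.000472), Rac (0.000603) and e14 (0.0012). Their medians (0.257, 0.179 and 0.138) were above that of the SOS bins, so by that measure the SOS bins did not stand out. The permutation p-values that follow come from random sets of bins in these same libraries. They measure spread between bins and not between cultures. In these libraries, the highest of 3 neighbouring bins at each of 16 loci gave values against a general rise at transcribed genes as the whole cause. The median excess over bins matched on ChIP over input in DL4201 was 0.179 (permutation p = 1e-04), and 0.111 at the own bins (permutation p = 0.0042). Against a slope along the chromosome, the excess over bins 4 to 50 bins away was 0.161 (permutation p = 8e-04). The values also argue against 1 deviating ChIP library as the cause of the rise relative to all bins far from lacZ. By that measure the median of these loci was 0.192 without DL4184 ChIP A and 0.227 without DL4184 ChIP B. These values are not the excess over matched bins, which is not given without either library. Whether LexA-regulated genes as a set carry more RecA ChIP signal in cells with the break stays open (the 0.335 above), and where single ones do, the signal may follow higher transcription of these genes and not RecA on their DNA, which these libraries leave open.

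The raised zone at copA, apart from the zone at lacZ, had a median of 1.19 against 0.39 in the 82 bins between. In the libraries of letter A and in those of letter B, the 25-bin window with the highest mean beyond the extent was the same (bins 1204 to 1228), and in the libraries not used to choose it, that window exceeded the bins between by 1.06 (B) and 0.609 (A), which argues against a tail that falls with distance from lacZ. The input difference in the zone was -0.0225, which argues against fewer input counts in DL4184, and the median was 0.908 without DL4184 ChIP B and 1.42 without DL4184 ChIP A, which argues against 1 deviating library. Because the strains differ in the break, a second place of RecA loading in DL4184 may underlie the zone. A difference in sequence between the strains near this zone was not tested and stays open.

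DL4184 ChIP library B exceeded A around lacZ, by a median log2 of 0.621 after scaling to bins far from lacZ, which argues against a difference in depth alone. B over A was also 0.424, 0.688, 0.622, 0.44 and 0.485 in the 5 terminus zones, where 0 bins were called between the strains. If the break leaves these zones unchanged, that argues against more cells with a break in that culture as the whole cause. The lack of calls cannot show this. In bins 2255 to 2277, for example, the DL4184 ratios (1.83 and 2.97) lay on either side of those of DL4201 (2.41 and 2.54), a spread that can hide a difference. The 5 zones lie within 100 bins of hipA. Of the next zones called in DL4201, bins 2094 to 2113 also had a higher median ratio in B (2.02, against 1.35 in A), and bins 2412 to 2423 did not (1.44, against 1.51). At ribosomal RNA bins B over A was -0.189 and at transfer RNA bins -0.225, so whether A holds a larger share of unspecific DNA may depend on whether the signal at those genes is itself unspecific, and stays open. In the zone at copA it was 0.549 and in the zone at dinB 0.377.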

How the results depend on the processing

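The crossed pairing of DL4201 letters, the lists without bins near lacZ, the same-letter input, the scalings of transfer RNA bins and the fits of far bins without 1 library were chosen after seeing the data, and the other alternatives before. RecA enrichment called 180 bins, against 1398 with total counts only, 105 at a threshold of 0.01 and 16 without bins within 500 bins of lacZ. Leaving out 1 library gave 105 to 264: 110 without DL4184 input A, 105 without DL4184 input B, 106 without DL4201 input A, 109 without DL4201 input B and 116 without DL4201 ChIP A. With 1 library left the group was assumed to vary like the others. Of the 180 bins, DESeq2 also called 175 and limma-voom 170. Blocks by column letter, in place of the planned repeat number, gave 134 bins, all higher (132 of them among the 180), and crossed letters 210. With those blocks all 5 falls lost their call (adjusted p between 0.0698 and 0.125), as did lacI, sbcC, recN, the bin of yafN and yafO, rpmI, rpmE and intF (between 0.0519 and 0.125), at nearly the same log2. The flank lists had an adjusted p of 0.175 with an estimated correlation, and 0.0738 in the direct ChIP comparison. Runs of at least 3 called bins far from lacZ also numbered 0. The direct ChIP comparison called 390 bins, against 2417 with total counts only, 204 with only the groups compared, 210 at 0.01 and 111 without bins near lacZ. Leaving out 1 library gave 239 (DL4201 ChIP A) to 501. The input gave 0 bins, with 1 when only the input libraries were fitted, and 0 without any 1 library. ChIP over input gave 2682 to 3259 bins in DL4184 and 2110 to 3076 in DL4201 with 1 library left out. The origin-distal extent of 44 bins was 94 by DESeq2, 71 with 21-bin windows and 37 to 89 with 1 library left out (89 without DL4184 ChIP A). The origin-proximal extent of 53 bins ran from 41 to 57 (57 with 21-bin windows). The first origin-proximal window (3.33) was 4.52 as a median over bins and 2.82 to 3.83 with 1 library left out, and the origin-distal one 2.94 to 3.97. The input slope on the replichore with lacZ was -0.0311 without bins near lacZ and -0.0467 (without DL4201 input A) to -0.0219 (without DL4201 input B). The other slope ran from -0.0329 to -0.0131 (without DL4201 input B), and the origin to terminus difference from 0.0325 to 0.109. Lists past the threshold with an estimated correlation fell from 7 to 2 in RecA enrichment and in ChIP, from 7 to 0 in input and in DL4184 and from 9 to 0 in DL4201. With the preset correlation and without bins near lacZ, 4 lists passed in input and 4 in DL4184, and with an estimated correlation 0 in both (smallest adjusted p = 0.574 and 0.0786). Of 1223 comparisons of named bins over 17 settings, 1091 kept direction and side of the threshold, 99 lost and 29 gained a call, and 4 changed sign. These were bins without a call under total counts only, at ymfK/ymfT/ymfL (-0.0277), ymfR/beeE/jayE (-0.0113), ynfU/cspB/cspF (-0.0482) and cspF/ynfS/ydfT (-0.00195). Apart from the thresholds and the sets of bins or libraries, which change the counts by their construction, the cause was not tested. All libraries in a fit share a common spread per bin, so leaving out an input library also changes the test of the ChIP libraries. Counting error at the median bin was up to 4.85% (DL4184 ChIP A), and bins that changed 1.5-fold were recovered in 42 of 50 simulated cases. The simulation gave each bin the same spread in all groups, while real libraries of DL4184 ChIP varied most. Differences above 1.5-fold were also left uncalled in the data, such as cynX (1.86, adjusted p = 0.0578) and rrsH (0.69, adjusted p = 0.264). Changes larger than 1.5-fold can therefore be missed as well.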

Other observations

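The test of transfer RNA genes in this part was chosen after the result was seen, as were the zones named. By the rule for DL4201, zones lay along the whole chromosome, with the highest median at ribosomal protein genes (bins 4145 to 4159, 2.188). Among them were bins 2094 to 2113 (0.887) and 2412 to 2423 (0.768), on either side of the terminus. Within 100 bins of hipA, in the terminus, lay 5 zones with more ChIP than input in both strains. The highest medians of these were in 2 of them. One (bins 2255 to 2277, yddL/yddG to digH) held the formate dehydrogenase genes fdn and the ddp genes, and peaked at dosP with 2.34 ± 0.181 in DL4201. Its median ChIP/input ratios were 1.83 and 2.97 in DL4184 and 2.41 and 2.54 in DL4201. The other (bins 2320 to 2342, dgcF to pinQ) held marRAB, the regulators of multiple antibiotic resistance, and peaked at sad/ptrR with 2.49 ± 0.162 in DL4201, with median ratios of 2.1 and 3.26 in DL4184 and 2.62 and 2.79 in DL4201. All 23 bins of each were called higher than input in both strains. The others were weaker: bins 2219 to 2234 (15 of 16 called in DL4184 and 16 in DL4201, ratios 1.02 and 1.35 against 1.22 and 1.3), 2349 to 2360 (12 of 12 in both, 1.3 and 1.72 against 1.46 and 1.47) and 2368 to 2393 (26 of 26 in both, 1.36 and 1.76 against 1.31 and 1.4). Between the strains, in RecA enrichment, edgeR, DESeq2 and limma-voom called 0 bins in each of the 5 zones, with 1 at an unadjusted p under 0.05 in bins 2368 to 2393 and 0 in the others, and the medians of the stronger ones were -0.03 and 0.01.

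Transfer RNA genes also carried more ChIP than input in the strain without the break. Of 43 bins with a transfer RNA gene and no ribosomal RNA gene, 37 (86%) were called higher in DL4201, against 1429 of 4533 other bins (31.5%, odds ratio 13.4, Fisher's exact test, p = 2.54e-13). The test treats bins as independent, although they come from the same libraries and bin 22, for example, adjoins a ribosomal RNA bin. Its p therefore does not measure variation between cultures. With total counts only, a scaling run after the result was seen, 36 and 722 bins were called. The median ratios of the transfer RNA bins were 4.44 and 3.56 in DL4184 and 3.04 and 3.75 in DL4201. With the ribosomal RNA and ribosomal protein genes, this suggests that the ChIP signal is high at strongly transcribed genes in general, and no control without antibody or without RecA was used here to tell such a background from RecA on DNA.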
